A study of Mus musculus with 6 samples.

How the data were processed

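H3K27ac ChIP-seq was done in RAW264.7 cells that were wild type or lacked Bmal1 or Mfp2, with 1 ChIP and 1 input library for each genotype. Groups were taken from the genotype and antibody labels. Per the labels' protocols, cells were grown in DMEM with 5% serum, fixed with 1% formaldehyde and sonicated, and libraries were made with the NEBNext Ultra II kit. The antibody is given as Abcam ab4729. Per the submitters' processing notes, fastp 1.0.1, BWA 0.7.19-r1273, SAMtools 1.23, Picard 3.4.0, MACS3 3.0.3 and HOMER 5.1 were used with build mm39, without a stated role or order. How duplicate reads and multiply mapped reads were treated is not given in the sources used here.

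The data analysed are 3 peak lists, 1 per ChIP library, with no pooling of libraries. Per the file headers, the authors called peaks with HOMER findPeaks in its histone style against the input of the same genotype. Windows of 500 bp with a Poisson p-value of at most 0.001 were stitched into regions, and per the file headers a region needed at least 4-fold enrichment and a p-value of at most 0.0001 over input. The lowest deposited fold over input was 4 in each list. The headers give a minimum of 10, 9 and 10 tags per window in wild type, Bmal1KO and Mfp2KO, fragment lengths of 236, 234 and 216 bp, and 1052, 826 and 753 putative regions removed by the input filter. Because each list has its own input and its own tag minimum, the same acetylation can pass in one list and miss in another, and absence of a peak is not absence of the mark.

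Several kinds of value were deposited with each peak. The normalized tag count is a signal that the authors scaled to 10 M tags per library, per the file headers. Input tags are also a deposited signal, given as counted in wild type and Mfp2KO and scaled to the depth of the ChIP library in Bmal1KO. The deposited fold over input is the ratio of ChIP to input tags after depth scaling, per the file headers. The authors' p-value over input was used only to describe the threshold. The findPeaks score is the authors' own value per peak, whose formula is not given in the sources used here. From the values it may describe a window rather than the whole region, since regions with very many tags can have low scores, but this was not tested. Score and fold were used only to describe, rank or filter peaks within a list.

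Depth per ChIP library was taken from the authors' headers: 15.8 M tags in wild type, 12.5 M in Bmal1KO and 15.8 M in Mfp2KO. Input depth was derived from the scaling of the tag columns and came to 14.9 M, about 12.9 M and 12.8 M tags. Normalization to a fixed total does not correct for a difference in the share of tags in peaks, and tag sums over separately called regions move with the length called, so called length and tags per kb are given beside them for named clusters and for quintiles.

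Peaks were compared by overlap of at least 1 bp. A wild-type peak without a knockout peak, and the reverse, was counted, and its share was given a 95% Wilson interval. No test between genotypes was possible, so no p-value is given for any difference. For wild-type peaks absent from both knockouts, the observed number was set beside that for independent lists (n1 × n2 / N), over all peaks and within 10 deciles of peak score. The same was fixed beforehand for regions in both knockouts alone, but there the N merged regions include those called in wild type, which cannot be of this kind, so the number moves with the length of the wild-type list. Circular shifts of the peaks, 100 of them, were also made for these regions and are not used, since they place peaks mostly in sequence that holds no peak in any list. Peaks of the lists were merged into regions where they overlapped. Windows of 5 Mb with at least 20 wild-type peaks were compared by the share of peaks absent from a knockout. Input per kb in windows of 5 Mb with at least 10 regions called in wild type and the knockout was used to look for copy number differences, relative to the median window, and minima of 1, 3 and 5 regions were also tried.

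The groups, the overlap rule, the ranking by score and 37 of the alternatives were chosen before the data were examined. Tags were at first used in place of the score while the data were explored. They give a sharper picture of where absent peaks lie, and they are reported as an addition. Also chosen after the data were seen were deciles of tags and of fold, the share expected in each window from tags, the comparison of the knockouts with each other, circular shifts of the peaks, clusters of peaks within 10 kb, and quintiles of shared regions by tags per kb. Clusters were first made in each list alone and quintiles first taken from the wild-type list, and both were replaced because they select on the list being compared. The joint clusters still select in part on the lists compared, since they were ranked by the sum of each list's share of tags. The values of the first versions are given with the alternatives.

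The rule for naming, fixed before the data were examined, took the 12 genes with the highest-scoring promoter peaks of each kind. As no gene could be assigned, it was applied to the peaks themselves: the 12 highest-scoring peaks absent from, or present only in, each knockout and both knockouts, and the 3 windows with the highest and lowest shares. Values are printed for a part of each 12. Clusters (5 at each end per knockout) and regions ranked by tags were named by rules chosen after the data were seen. Coordinates are those of the lists.

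An annotation and a genome of mm39 were not used here, and the gene table at hand is of GRCm38.p6, so H3K27ac at the targeted genes and at promoters, the 24 gene lists and 12 motifs fixed beforehand, and the position of peaks relative to genes were not analysed here. No column outside the labelled samples was found.

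Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The overlap step was tested on simulated data, in 5 runs on the 29276 wild-type peaks. The 200 peaks removed and 200 added per run were all recovered (100%), and no kept peak was called absent. The joint ratio for independent removal lay between 0.994 and 1.01. Added peaks lay on a chromosome of their own and kept peaks moved by at most 200 bp. The runs therefore check the code only, and not lists that differ in depth, width or threshold.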

Results

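Acetylation of histone H3 at lysine 27 (H3K27ac), a mark of active promoters and enhancers, was profiled by ChIP-seq in RAW264.7 cells, a macrophage-like mouse line, in 3 genotypes. The cells were wild type, Bmal1 knockout or Mfp2 knockout. BMAL1 is a core transcription factor of the circadian clock, and MFP2, encoded by Hsd17b4, is an enzyme of peroxisomal β-oxidation. The title of the series ties BMAL1 to macrophage inflammation through movement of MFP2 into the nucleus, and the labels state no inflammatory stimulus. Each genotype had 1 ChIP library and 1 input library, 6 libraries in all. The ChIP libraries held 15.8 M tags in wild type, 12.5 M in Bmal1KO and 15.8 M in Mfp2KO. With 1 library per genotype there is no replicate spread, so no difference below was tested between genotypes. The labels do not say whether a knockout is 1 clone or a pool of cells, so each difference is between these libraries and, where they are clones, between clones. The 95% Wilson intervals on shares cover the counting of peaks only. All positions are in mouse build mm39, and no peak was assigned to a gene, because the gene table used here is of another build. H3K27ac at the Bmal1 and Hsd17b4 genes, which would have checked the knockout labels, was not analysed here.

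Both knockout lists had fewer H3K27ac peaks than wild type, with a lower median width. Wild type had 29276 peaks covering 65.2 Mb. Bmal1KO had 25666 peaks covering 45.6 Mb, or 69.9% of the wild-type length, and Mfp2KO had 24477 peaks covering 45.2 Mb, or 69.3%. The difference was largest among the longest domains: 2148 wild-type peaks were longer than 5 kb, against 700 in Bmal1KO and 816 in Mfp2KO. Beyond 10 kb there were 325 wild-type, 47 Bmal1KO and 60 Mfp2KO peaks. The longest wild-type peak spanned 44494 bp, compared with 19511 bp in Bmal1KO and 24404 bp in Mfp2KO. The median width was 1707 bp in wild type, 1421 bp in Bmal1KO and 1613 bp in Mfp2KO. At the lower quartile the widths were 661, 630 and 733 bp, so the short peaks of Mfp2KO were not shorter than those of wild type. Tag density went the other way, most of all in Mfp2KO. Median tags per kb were 23.9, 26.1 and 38.2 in wild type, Bmal1KO and Mfp2KO, in units of tags per 10 M tags of the library. In the authors' deposited headers the approximate share of tags in peaks was 38.7% in wild type, 37.4% in Bmal1KO and 57.2% in Mfp2KO.

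The first comparison asked which H3K27ac peaks differ without BMAL1. Of the wild-type peaks, 11386 had no overlapping Bmal1KO peak, or 38.9% (95% Wilson interval 38.3 to 39.5). In the other direction, 6066 Bmal1KO peaks had no wild-type peak, or 23.6% (23.1 to 24.2). The wild-type peaks without a Bmal1KO peak were short and weak, with a median of 637 bp and 10.4 tags, whereas those with one had a median of 2661 bp and 118 tags. They held 4.98% of the tags in wild-type peaks. The share without a Bmal1KO peak went from 58.6% in the lowest decile of the authors' peak score to 12.4% in the highest, where 362 of 2927 peaks were concerned. Ranked by tags instead, a choice made after the data were seen, it went from 93.0% to 0.0342%, or 1 of 2927 peaks. Long peaks hold more tags and have more sequence in which to meet another peak.

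Named regions were the highest-scoring peaks of each kind. Among the 12 highest-scoring wild-type peaks without a Bmal1KO peak, 8 had a peak in Mfp2KO, against 2273 of all 11386 such peaks, or 19.96%. Score alone moves this share: 41.4% of all wild-type peaks had no Mfp2KO peak, against 11.5% in the highest decile of score. The top one of the 12 lay on chromosome 4 (108637246-108638808), with a score of 83.5, 90.5 tags and 4.56-fold enrichment over input. It had no peak in either knockout, but a Bmal1KO peak began or ended 23 bp away. On chromosome 15 (81578253-81579186) a peak with 105 tags was also absent from both knockout lists, and the nearest Bmal1KO and Mfp2KO peaks were 29020 and 29081 bp away. On chromosome 3 (94394050-94396797) wild type had 226 tags over 2747 bp and Mfp2KO had 838 tags over 6876 bp, with the nearest Bmal1KO peak 2719 bp away. On chromosome 6 (72211834-72213258) wild type had 142 tags, Mfp2KO 73.5 tags, and no Bmal1KO peak lay within 70038 bp. Enrichment over input was under 6-fold for 10 of the 12, where the authors' limit was 4-fold.

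Over peaks of any score, 1046 of 6066 Bmal1KO peaks without a wild-type peak had a peak in Mfp2KO, or 17.2%. Of the 12 highest-scoring ones, 9 did. The top one, on chromosome 11 (3142967-3144219), stood apart with 3275 tags in 1252 bp and a score of 932.5 (next 118), and had 4.51-fold enrichment with 910.5 input tags, or 727 per kb against a list median of 5.40. The nearest wild-type peak was 6907 bp away. On chromosome 4 (35156952-35158107) Bmal1KO had 98.1 tags with 7.91-fold enrichment and Mfp2KO had 203 tags, with the nearest wild-type peak 7568 bp away. On chromosome 9 (110610394-110611278) the values were 84.6 tags in Bmal1KO and 364 in Mfp2KO, with no wild-type peak within 20654 bp. In all 12, enrichment lay between 4.12-fold and 7.91-fold. Of all Bmal1KO peaks, 34.6% had no Mfp2KO peak, against 11.9% in the highest decile of score.

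**Figure D1:**
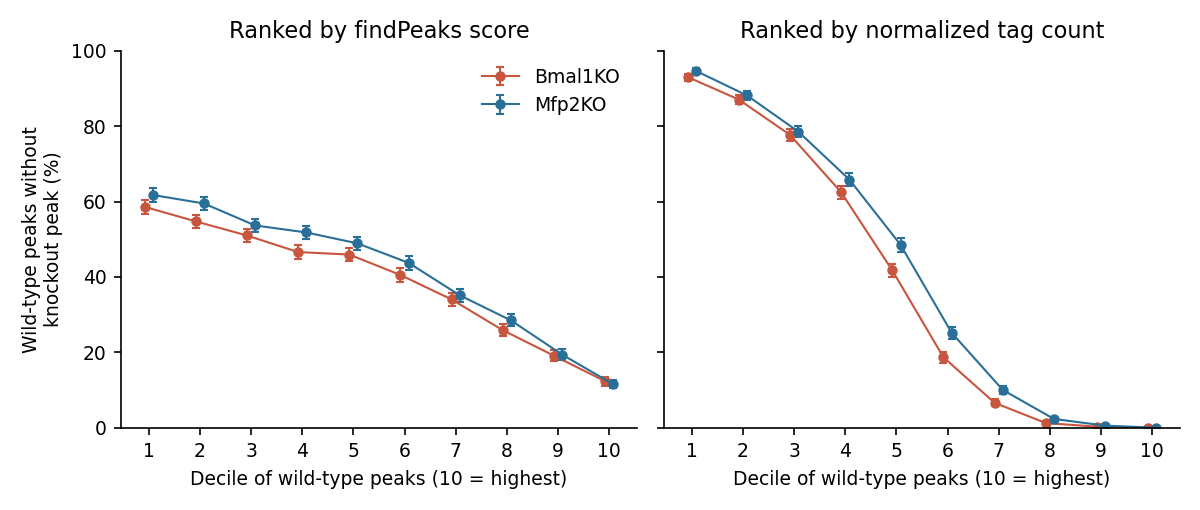
Share of wild-type H3K27ac peaks without an overlapping peak in Bmal1KO or Mfp2KO (percent, vertical axis) in each decile of wild-type peaks by the authors' score (left) or by normalized tag count (right); points are 1 library per genotype and bars are 95% Wilson intervals. The shares go from 58.6% and 61.7% to 12.4% and 11.5% across deciles of score, and from 93.0% and 94.7% to 0.0342% in both knockouts across deciles of tags.

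The second comparison asked the same of cells without MFP2. No Mfp2KO peak overlapped 12121 wild-type peaks, or 41.4% (40.8 to 42.0), and 6221 Mfp2KO peaks, or 25.4% (24.9 to 26.0), had no wild-type peak. As in Bmal1KO, the wild-type peaks concerned were short and weak, with a median of 649 bp and 10.8 tags against 2687 bp and 126 tags for those with an Mfp2KO peak. They held 5.88% of wild-type peak tags. The share went from 61.7% in the lowest to 11.5% in the highest decile of score, and by tags from 94.7% to 0.0342%. The Mfp2KO library had 0.999 times the tags of the wild-type library, and the Bmal1KO library 0.794 times.

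Of the 12 highest-scoring wild-type peaks without an Mfp2KO peak, 8 had a peak in Bmal1KO, against 3008 of all 12121, or 24.8%. Here too score alone moves the share: 38.9% of all wild-type peaks had no Bmal1KO peak, against 12.4% in the highest decile of score. On chromosome 13 (55619591-55620972) wild type had 120.0 tags, Bmal1KO 130 tags over 1909 bp, and the nearest Mfp2KO peak was 5227 bp away. On chromosome 15 (99481667-99482167) wild type had 48.4 and Bmal1KO 94.5 tags, with no Mfp2KO peak within 65994 bp. On chromosome 12 (73158752-73159786) the values were 77.6 tags in wild type and 201 in Bmal1KO, with the nearest Mfp2KO peak 10529 bp away. For 11 of the 12, enrichment over input was under 6-fold in wild type.

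Over peaks of any score, 918 of 6221 Mfp2KO peaks without a wild-type peak had a peak in Bmal1KO, or 14.8%. Of the 12 highest-scoring ones, 7 did. The highest, on chromosome 14 (33041739-33042870), had 188 tags in Mfp2KO and 94.5 in Bmal1KO, with the nearest wild-type peak 3244 bp away. A peak on chromosome 9 (8017478-8017978) had the strongest enrichment of the 12, 14.58-fold, with 114 tags in Mfp2KO and 25.1 in Bmal1KO, and no wild-type peak within 143371 bp. On chromosome 16 (31247613-31249056) Mfp2KO had 166 tags and wild type had no peak within 76069 bp, while a Bmal1KO peak lay 309 bp away. On chromosome 2 (103953143-103954020) Mfp2KO had 118 tags, and the nearest peaks were 10087 bp away in wild type and 11690 bp away in Bmal1KO. Enrichment was under 6-fold for 11 of these 12. Of all Mfp2KO peaks, 32.1% had no Bmal1KO peak, against 21.7% in the highest decile of score.

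Whether both knockouts differ from wild type at the same places was asked next. Neither knockout had a peak at 9113 wild-type peaks, or 31.1% (30.6 to 31.7), whereas 2273 lacked a peak only in Bmal1KO and 3008 only in Mfp2KO. Independent lists of 11386 and 12121 among 29276 peaks would share 4714, and 5416 within deciles of score, a ratio of observed to expected of 1.68. Within deciles of tags, a choice made after the data were seen, 8569 were expected, a ratio of 1.06. Among the upper 50% of wild-type peaks by score, 2560 were absent from both knockouts where 1236 were expected within deciles of score. Within deciles of tags of this same upper 50% by score, 2283 were expected, a ratio of 1.12. Among the upper 50% by tags, 305 were absent from both knockouts where 158 were expected within deciles of tags. Both comparisons used the same wild-type library, which cannot be divided. Unchanged libraries cannot be simulated from peak lists, so part or all of the excess may come from the shared library.

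After peaks of all 3 lists were merged, 39754 regions remained, of which 14789 were called in every genotype and 9113 in wild type alone. Bmal1KO alone had 5020 and Mfp2KO alone 5303. In both knockouts and not in wild type, 811 regions were called. Independent lists among the 39754 regions would share 897, but these include regions called in wild type, so this is not the number for unchanged genotypes, and alternatives lay on both sides of it, such as 1807 against 1356 in the upper 50% of each list by score. The count followed list length and ranking, with 2358 for equal numbers of peaks by score, 850 for equal numbers by tags, and 111 when only the upper 50% by tags was looked up. The knockouts also differed from each other: 34.6% of Bmal1KO peaks had no Mfp2KO peak and 32.1% of Mfp2KO peaks had no Bmal1KO peak. The sequence shared by a pair of lists, relative to their joint length, was 53.1% for wild type and Bmal1KO, 48.1% for wild type and Mfp2KO, and 53.6% for the knockouts.

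**Figure D2:**
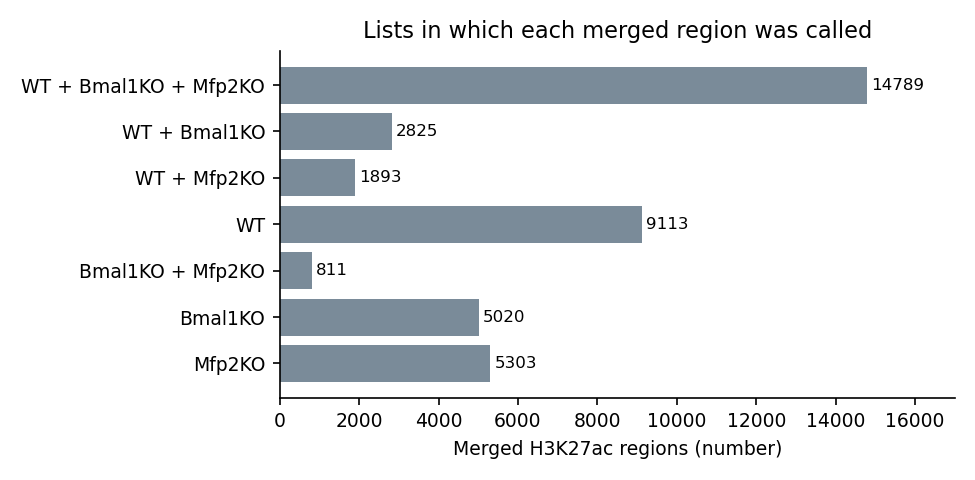
Number of merged H3K27ac regions (horizontal axis) by the genotypes in whose list each was called, with 1 library per genotype. Regions called in all genotypes number 14789, those in wild type alone 9113 and those in both knockouts but not wild type 811, a count that went from 111 to 2358 with other rankings and list lengths.

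Wild-type peaks absent from both knockouts included, by score, regions on chromosome 4 (21678204-21681370), with 222 tags over 3166 bp, and on chromosome 1 (91293897-91294904), with 70.3 tags. The region on chromosome 13 (117160916-117163144) had 116 tags and no Mfp2KO peak within 1359402 bp, and the nearest Bmal1KO peak was 61017 bp away. The one on chromosome 11 (95036441-95037835) had the strongest enrichment of the 12, 11.32-fold, with 122 tags and no knockout peak within 56479 bp. Regions called in both knockouts and not in wild type were led by chromosome 8 (106862939-106863967), with 116 tags in Bmal1KO and 42.5 in Mfp2KO and a wild-type peak 1000 bp away. Chromosome 15 (58077905-58079505) followed with 93.7 and 93.5 tags, then chromosome 17 (28988776-28989652) with 64.6 and 43.7 tags. Chromosome X (169108358-169110705) had 246 tags in Bmal1KO and 129 in Mfp2KO.

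The share of wild-type peaks absent from a knockout varied along the genome. Over 417 windows of 5 Mb with at least 20 wild-type peaks the median was 39.2% for Bmal1KO and 42.3% for Mfp2KO. The window from 65 to 70 Mb of chromosome 1 had the highest share in both, with 74.6% (63.1 to 83.5) of 67 peaks absent from Bmal1KO and 85.1% (74.7 to 91.7) absent from Mfp2KO. From the tags of its peaks, 59.0% and 61.5% were expected. Next came chromosome 13 from 25 to 30 Mb, with 71.9% (54.6 to 84.4) and 78.1% (61.2 to 89.0) of 32 peaks. There 59.2% and 61.4% were expected, inside the intervals. Then came chromosome 6 from 105 to 110 Mb in Bmal1KO, with 69.4% (58.0 to 78.9) of 72 peaks and 52.0% expected. Chromosome 7 from 50 to 55 Mb in Mfp2KO had 76% (56.6 to 88.5) of 25 peaks, with 63.4% expected, inside the interval. Bmal1KO was at 48% (30.0 to 66.5) there, with 61.1% expected. The windows on chromosomes 1, 13 and 7 held 9, 7 and 5 regions called in every list, under the 10 needed for an input value over all lists, so no copy number is given for them. The lowest shares in Bmal1KO were on chromosome 12, from 5 to 10 Mb and from 20 to 25 Mb. Each was 14.3% (4.98 to 34.6) of 21 peaks, with 32.6% and 28.8% expected, inside the interval. Next was chromosome X from 5 to 10 Mb, at 15.6% (7.75 to 28.8) of 45 peaks, with 29.7% expected. Wild-type input per kb in this window was 0.564 times the median window, and whether this moves the share expected from tags was not tested. In Mfp2KO the lowest was 10% (2.79 to 30.1) of 20 peaks from 175 to 180 Mb of chromosome 2, with 36.3% expected. Chromosome 17 from 20 to 25 Mb had 10.3% (5.08 to 19.8) of 68 peaks, with 25.9% expected. Chromosome 4 from 155 to 160 Mb had 17.0% (9.20 to 29.2) of 53 peaks, with 25.9% expected, inside the interval. All these windows are extremes of the 417, a choice that the intervals do not allow for.

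Most strong H3K27ac clusters covered less sequence in the knockouts, with tags that were close to wild type in Bmal1KO and higher in Mfp2KO at the median. Peaks of all lists within 10 kb of each other were joined and the 500 clusters with most tags were kept, a step chosen after the data were seen. Tags were summed over the 3 lists, each as a share of the tags of its list. A cluster low in both knockouts could thus be kept mainly through its wild-type tags. Of the 500 clusters, 427 covered less sequence in Bmal1KO than in wild type and 360 in Mfp2KO. Their called length was 8.86 Mb in wild type, 6.76 Mb in Bmal1KO and 7.33 Mb in Mfp2KO. In the knockouts this was 76.2% and 82.7% of wild type, above the 69.9% and 69.3% of the whole lists. The lower length was therefore not particular to these clusters. In wild type, Bmal1KO and Mfp2KO the clusters held 19.5%, 20.5% and 21.2% of the tags in peaks on chromosomes 1 to 19 and X. The median ratio of tags to wild type was 1.05 in Bmal1KO and 1.65 in Mfp2KO. These ratios are on tags scaled to the library total, of which Mfp2KO had more in peaks. When each list was clustered alone, more than 500 clusters were kept per list, and fewer in each knockout than in wild type. The called length in Bmal1KO was then 54.4% of wild type, against 76.2% with joint clusters, and in Mfp2KO 61.5% against 82.7%. Because the numbers of clusters differ, the values from lists clustered alone are not the same measure. Among the 5 clusters with the lowest tags relative to wild type, 3 were the same in both knockouts, where independent comparisons would share 0.05. Both ratios are over the same wild-type tags, so a high wild-type value alone places a cluster low in both. On chromosome 16 (24716237-24886204) 27 wild-type peaks covered 113.6 kb with 4302 tags. Bmal1KO had 15 peaks, 55.7 kb and 1847 tags there, and Mfp2KO 15 peaks, 32.4 kb and 1529 tags, and tags per kb were 37.9, 33.2 and 47.1 in the 3 genotypes. On chromosome 10 (120421830-120534726) the called length was 61.4 kb in wild type, 36.2 kb in Bmal1KO and 27.4 kb in Mfp2KO, with 3047, 1253 and 974 tags, or 49.6, 34.6 and 35.6 per kb. On chromosome 19 (8994583-9061347) it was 62.8, 31.0 and 32.6 kb, with 3263, 906 and 1099 tags, or 51.9, 29.3 and 33.7 per kb. On the log2 scale this last cluster was at -1.85 in Bmal1KO (95% counting interval -1.94 to -1.76) and -1.57 in Mfp2KO (-1.65 to -1.49) relative to wild type. Relative to the median cluster of each knockout it was at -1.92 and -2.29. The cluster on chromosome 10 was at -1.36 and -2.37 on that scale, and the one on chromosome 16 at -1.30 and -2.22.

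**Figure D3:**
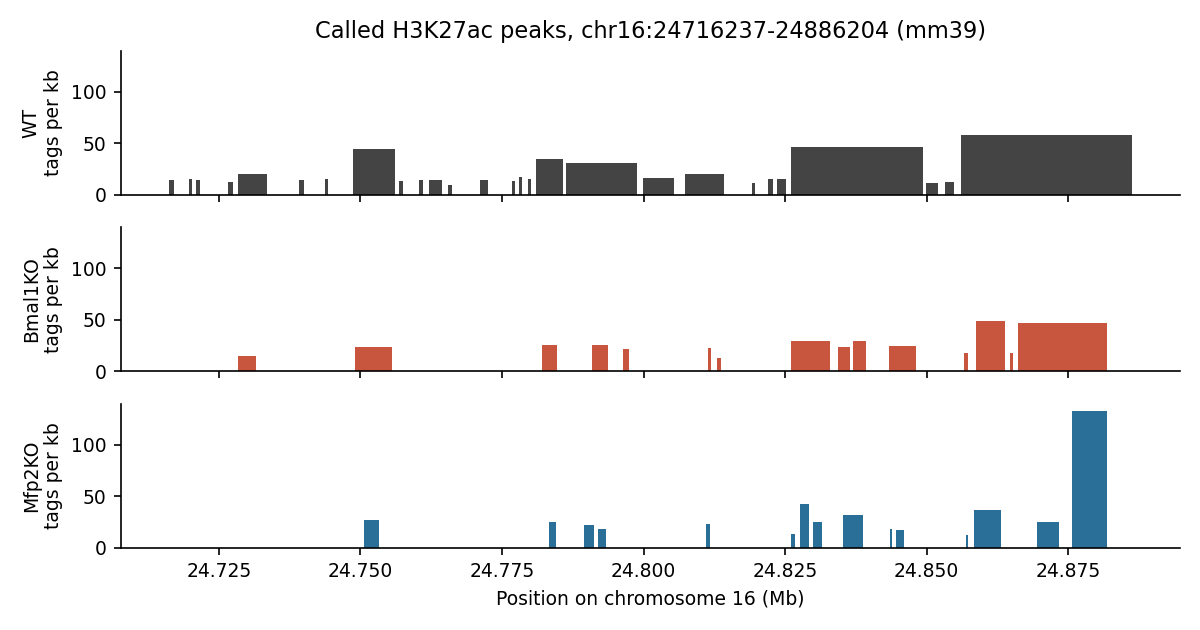
Called H3K27ac peaks on chromosome 16 from 24716237 to 24886204 (mm39, horizontal axis in Mb) in wild type, Bmal1KO and Mfp2KO, with the normalized tags per kb of each peak as its height. The 27 wild-type peaks cover 113.6 kb, and the 15 peaks of each knockout cover 55.7 kb in Bmal1KO and 32.4 kb in Mfp2KO.

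Regions called in all genotypes differed by how dense their acetylation was. In 14779 such regions on chromosomes 1 to 19 and X, the called length was shorter than in wild type in 77.8% for Bmal1KO and 78.7% for Mfp2KO. They were divided into quintiles by tags per kb in the knockout outside the comparison, again after the data were seen. In the sparsest quintile the median log2 ratio of tags to wild type was -1.003 in Bmal1KO and -0.95 in Mfp2KO, and in the densest it was 0.41 and 0.82. In the sparsest regions the median called length was 2449 bp in wild type against 1399 bp in Bmal1KO, and 2193 bp against 1286 bp in Mfp2KO. Pooled tags per kb in the sparsest quintile were 27.9 in wild type and 23.0 in Bmal1KO, and in the other comparison 25.9 in wild type and 31.1 in Mfp2KO. In the densest quintile they were 131 and 183 for Bmal1KO, and 137 and 288 for Mfp2KO. At the median region the log2 ratio of tags per kb was -0.26 in the sparsest and 0.57 in the densest quintile for Bmal1KO, and -0.18 and 1.13 for Mfp2KO, so that in the sparsest quintile of Mfp2KO the pooled value was above wild type and the median region below it. With quintiles from the wild-type list the densest quintile was at 0.018 in Bmal1KO, and with tags scaled to the shared regions' total the densest quintile in Mfp2KO was at 0.21 and the sparsest at -1.56.

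**Figure D4:**
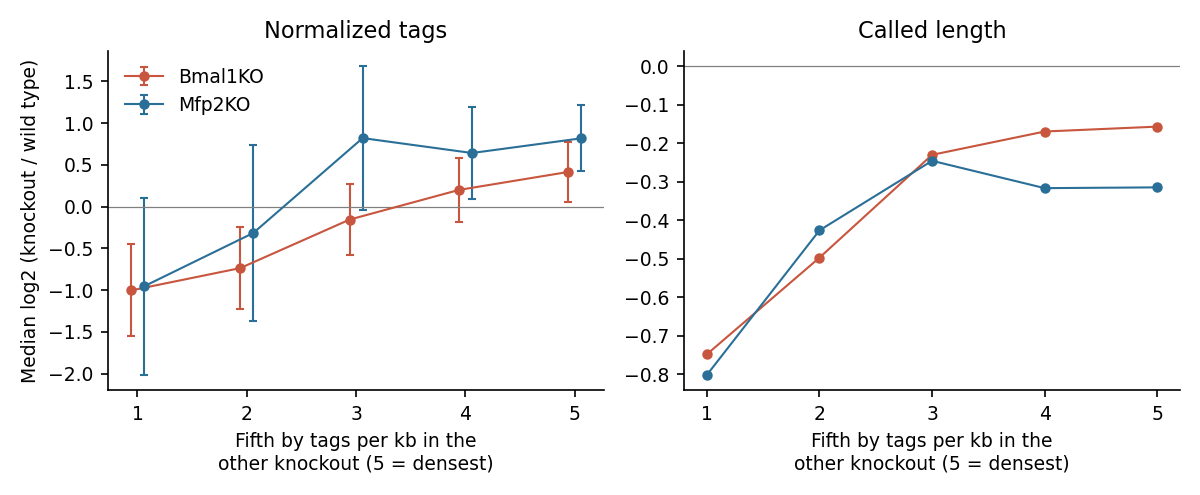
Median log2 ratio of normalized tags (left) and of called length (right), knockout over wild type, in quintiles of 14779 regions called in all genotypes, by tags per kb in the other knockout; bars on the left are the median absolute deviation across regions, which are not replicates. Tags go from -1.003 to 0.41 in Bmal1KO and from -0.95 to 0.82 in Mfp2KO, and called length lies below 0 in every quintile.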

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

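Each genotype had 1 library, so no sample was compared with others of its group, and the peaks given here were noticed only after the data were seen. Outside chromosomes 1 to 19 and X each list had 3 peaks, on 2 unplaced scaffolds, with input tags per kb over 10 times the list median. No comparison above uses their input signal, but the peaks themselves are counted in the main overlap comparisons. The deposited input tags of the strongest were 2667.5 in wild type, 2413.7 in Bmal1KO and 3842 in Mfp2KO, where a count of 0 allows up to 3. Input tags per kb were 1272, 1194 and 1916, against list medians of 5.93, 5.40 and 7.19. A weaker peak of the same scaffold had 118.5, 97.2 and 153.5 input tags, and the peak on the other scaffold 687, 450.4 and 735.5. The strongest peak held 0.379%, 0.666% and 0.468% of the normalized tags in the lists of wild type, Bmal1KO and Mfp2KO, and leaving out all scaffolds is among the alternatives. On chromosomes 1 to 19 and X, 3 peaks in wild type, 5 in Bmal1KO and 8 in Mfp2KO also had input tags per kb over 10 times the list median. These are in the comparisons too. The strongest of them was in Bmal1KO on chromosome 11 (3142967-3144219), with 727 input tags per kb.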

How the results depend on the processing

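Of 81 alternatives, 37 were planned and 44 were chosen after the data were seen; these are every ranking by tags or fold and every setting for clusters and quintiles. No log2 value changed sign, 11 alternatives stayed within the interval or within 1.5 times the main count, and 58 moved further. For the other 12, which are called lengths, there is no interval to compare with, and their values are given; where the construction does not show why, the cause was not tested. Shares are given in the order wild-type peaks absent from Bmal1KO, from Mfp2KO, Bmal1KO and Mfp2KO peaks absent from wild type, and wild-type peaks absent from both knockouts. With only the upper 50% of each list by score they were 53.7%, 57.2%, 44.4%, 48.0% and 37.4%, and 1807 regions were in both knockouts alone, since a peak below the median counts as absent. With equal numbers of peaks by score they were 37.4%, 37.5%, 31.5%, 33.5% and 27.6%, with 2358 regions. With the upper 50% by score only in the list looked up they were 26.4%, 27.7%, 16.7%, 22.9% and 17.5%, with 285 regions. Ranked by tags, the same 3 settings gave 20.8%, 27.2%, 6.11%, 10.9% and 16.0% with 332 regions, then 29.6%, 31.4%, 22.9%, 26.6% and 21.2%, then 5.38%, 7.64%, 2.28%, 4.13% and 2.08% with 111 regions. Equal numbers by fold gave 35.9%, 37.9%, 29.4% and 32.6% for the first 4 shares. A reciprocal overlap of 50% gave 55.9%, 59.2%, 49.7%, 51.2% and 48.6%, and it gives no value for merged regions. Allowing a gap of 500 bp gave 36.5%, 39.2%, 21.0%, 22.8% and 28.0%. On chromosomes 1 to 19 and X all these values stayed within their limits. Called length in Bmal1KO and Mfp2KO was 69.4% and 66.3% of wild type in the upper 50% by score, and 68.4% and 64.5% by tags.

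For the 500 strongest clusters, called length in Bmal1KO and Mfp2KO was 76.7% and 80.3% of wild type with peaks joined within 5 kb. It was 74.1% and 80.9% within 20 kb, and 75.3% and 79.8% for 1000 clusters. With each list clustered alone it was 54.4% and 61.5%. That setting kept more than 500 clusters per list, and fewer in each knockout than in wild type. For the quintiles of shared regions, taking them from the wild-type list gave -0.78 and 0.018 for the sparsest and densest in Bmal1KO and -0.58 and 0.45 in Mfp2KO. Taking them from input tags per kb gave 0.30 for the densest in Bmal1KO, and -1.10 and 0.95 for the sparsest and densest in Mfp2KO. Scaling tags to the total of the shared regions gave -1.56 and 0.21 in Mfp2KO.

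No paired analysis was possible because each genotype had 1 ChIP library and no replicate numbers. Alternatives for promoters, gene lists, motifs and genomic location were not run, since they need an annotation or genome of mm39. Depth limits the weak peaks: a window needed 10 tags in wild type and Mfp2KO and 9 in Bmal1KO, which had the shallowest library.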

Other observations

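Apart from the pooled test of library bias and the test of input at strong peaks ranked by tags, every test and ranking in this part was chosen after the result was seen.

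Regions with many tags that were absent from a knockout list were few, and some lay far from any knockout peak. On chromosome 3 (148693153-148696335) wild type had 309 tags, while the nearest peak was 2134437 bp away in Bmal1KO and 2173116 bp away in Mfp2KO. On chromosome 17 a wild-type peak starting at 72172155 had 278 tags and no knockout peak within 179869 bp. On chromosome 10 (31483257-31486934) wild type had 505 tags and Mfp2KO 481, and no Bmal1KO peak lay within 292533 bp. On chromosome 13 a wild-type peak starting at 51946153 had 262 tags and Bmal1KO 273, with the nearest Mfp2KO peak 47945 bp away. In the other direction, Mfp2KO had 463 tags at a peak starting at 82654300 on chromosome 11, where the nearest peak was 12626 bp away in wild type and 14237 bp away in Bmal1KO. A region on chromosome 5 (107871946-107875594) had 277 tags in Bmal1KO and 507 in Mfp2KO and no peak in wild type.

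Among the 500 strongest clusters, 277 had more tags in both knockouts than in wild type and 45 had fewer in both, against 253 and 20.8 for independent comparisons, and 6 were over 2-fold in both. Both comparisons used the same wild-type library, which by itself moves a cluster the same way in both. Relative to the median cluster of each knockout, which was at 1.05-fold in Bmal1KO and 1.65-fold in Mfp2KO, 3 were over 2-fold in both, and the clusters over 2-fold went from 7 to 5 in Bmal1KO and from 146 to 6 in Mfp2KO. Clusters under 50% of wild type went from 9 to 11 in Bmal1KO and from 6 to 23 in Mfp2KO, so on this scale more lay below that limit than above 2-fold in both. On chromosome 8 (19833717-19835793) tags were 2.88-fold wild type in Bmal1KO and 4.90-fold in Mfp2KO, over 1.42 kb in wild type, 2.03 kb in Bmal1KO and 1.84 kb in Mfp2KO, with 521, 1050 and 1965 tags per kb. Relative to the median cluster its log2 values were 1.45 and 1.57, and its peaks had 100, 66.9 and 119 input tags per kb in wild type, Bmal1KO and Mfp2KO, where list medians were 5.93, 5.40 and 7.19. A second region of chromosome 8 (20697097-20699484) was at 2.65-fold and 4.58-fold over 1.30, 2.28 and 2.31 kb, with 372, 561 and 960 tags per kb, and had 78.3 input tags per kb in wild type and 76.7 in Mfp2KO. Chromosome 11 (5046710-5060080) was at 2.23-fold and 3.88-fold over 5.12, 3.23 and 4.72 kb, with 139, 491 and 585 tags per kb. In Mfp2KO, chromosome 6 (125107243-125147052) was at 3.70-fold with 16.1 kb called and 152.6 tags per kb, against 11.98 kb and 55.6 tags per kb in wild type, a log2 value of 1.89, or 1.16 relative to the median cluster. On chromosome X, 36.4% of wild-type peaks were absent from each knockout, against 42.1% and 45.3% expected from their tags. There 56 of 452 Bmal1KO peaks (12.4%) had no wild-type peak, where 22.7% were expected. Input per kb on chromosome X was 0.58, 0.62 and 0.63 times the median chromosome in wild type, Bmal1KO and Mfp2KO. Its peaks may thus hold fewer tags at the same acetylation in all 3 genotypes, and whether this moves the expected shares was not tested.

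Both knockout lists covered less sequence than wild type. Lower total depth was argued against for Mfp2KO, whose library had 0.999 times the wild-type tags. Weaker enrichment was argued against only for regions called in every list. Their normalized tags were 1.52 times wild type in sum and 1.36 times at the median region. In the sparsest quintile of these regions the median log2 ratio of tags was -0.95, and 29.1% of regions rose. Pooled tags per kb in that quintile were 31.1, against 25.9 in wild type. For sparse sequence, weaker enrichment and genotype cannot be told apart, because Mfp2KO tags were deposited only where an Mfp2KO peak was called. For Bmal1KO, with 0.794 times the wild-type tags, depth and genotype cannot be told apart, because no deeper Bmal1KO library was analysed here. In Bmal1KO the normalized tags in regions called in every list were 0.996 times wild type in sum and 0.875 times at the median region. Weaker enrichment over much of the genome and genotype therefore cannot be told apart. A shift of tags into the densest parts of the genome, from the knockout or from the preparation of single libraries, may account for it and was not tested.

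Sparse shared regions had fewer tags relative to dense ones in both knockouts. If fragment or sequence bias affected input and ChIP libraries alike, input should show the gap too. The input gap was 0.227 in Bmal1KO against 0.764 for ChIP tags per kb, under 50% of it, but 0.679 against 0.810 in Mfp2KO. From medians over regions, added after the pooled values were seen, the gaps were 0.299 for input against 0.831 for ChIP in Bmal1KO and 0.994 against 1.31 in Mfp2KO. In Mfp2KO, pooled log2 ChIP tags per kb relative to wild type were 0.27, 1.02 and 1.08 in the sparsest, middle and densest quintiles. Input was at -0.018, 0.26 and 0.66. The ChIP gap thus lay mostly below the middle quintile, and the input gap more above it. Input per kb was taken over the length called in each list, which differed between genotypes. Only regions that had passed 4-fold over their own input were included. The input gap can thus move with called length and with this filter. Bias shared by input and ChIP therefore stays open in both knockouts, and these gaps cannot decide on it. Bias of a ChIP library alone cannot be told apart from genotype in either knockout, because input would not show it. The effect of the genotypes, with 1 library each, was not tested.

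Some strong wild-type peaks had no knockout peak, and there high input in the knockout and genotype cannot be told apart, because knockout input was deposited only where a knockout peak was called. In the upper 50% by tags, wild-type input per kb at these peaks was 0.989 times that of other peaks of the same decile for Bmal1KO and 0.788 times for Mfp2KO, and by score 0.773 and 0.727 times; ChIP tags per kb were 0.851 and 0.769 times by tags, and 0.552 and 0.535 times by score. For loss of whole 5 Mb windows, none of the 3864 such peaks by score for Bmal1KO and 4051 for Mfp2KO lay in a window measured with input under 0.67 times wild type, but 2.59% and 3.73% lay in windows with under 10 shared regions and so without a value, and there deletion and genotype cannot be told apart. The minimum of shared regions sets this share: of 4 minima tried, those of 1, 3 and 5 regions gave 0.233%, 0.466% and 0.725% for Bmal1KO and 0.321%, 0.617% and 1.04% for Mfp2KO, peaks under 0.67 included. Smaller deletions, a fold near the authors' limit and the genotypes may each account for single peaks: in the upper 50% by score, 70.2% of peaks absent from Bmal1KO were under 6-fold over input, against 28.4% of those present, and 65.2% against 29.5% for Mfp2KO.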
